A study of Mus musculus with 18 samples.

How the data were processed

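RNA from the caudal corpus callosum of CPZ-fed WT and Trem2 KO mice was extracted with a silica-membrane column kit, amplified with a whole-transcript kit for small RNA amounts and labelled with biotin, per the labels' protocols. Each of the 18 samples was hybridised to 1 array of 1 colour. The values analysed are the authors' deposited log2 probe-set values, 241576 probe sets in 18 arrays, with values from 0.732 to 13.674. How the authors corrected background, normalized arrays and summarised probes is not given in the sources used here. Array medians ran from 5.26 to 5.41, a range of 0.148, so the deposited log2 values were used without further normalization. Array background levels are not in the table used here, so no statement is made on which genes lie above background. Differences with a group mean close to or under the filter level given below are read as uncertain in size.

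Probe sets were named from the platform's gene annotation. Of them 212097 had 1 gene symbol, 4475 had several and 25004 had none, and only the first kind was used for genes. The annotation is old, and 2668 symbols were updated through a RefSeq gene table of mouse assembly GRCm38.p6, which was used for names and for which genes neighbour each other and not for coordinates. Of 20416 gene symbols 20289 were current in that table and 127 were not found in it and kept as deposited. The value of a gene in an array is the median of its probe sets, 8 per gene at the median, with 2292 genes resting on 1 probe set. The 20% of genes with the lowest mean over all arrays (log2 of 3.41 or less) were left out, which left 16332.

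Groups come from the genotype and stage in the labels. One limma model (version 3.58.1, in R 4.3.3) was fitted to all 18 arrays with 4 group means, 14 residual degrees of freedom and 5.6 prior degrees of freedom. It gave KO against WT at 6 and at 12 weeks, 12 against 6 weeks in WT and in KO, and the genotype by stage interaction, all two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Where the text says that a gene passed, it means this test. Fold sizes and log2 differences are on the deposited scale. Gene lists of cell types and functions, 35 in all with 505 genes, were written from textbook knowledge, and the 31 with at least 5 measured members were tested with camera at an inter-gene correlation of 0.01, adjusted over lists. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. List scores are the mean over members of log2 values centred on each gene's mean, and groups of scores were compared with exact two-sided permutation tests.

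The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The rule names Trem2 and its gene family, the 10 largest changes each way among genes passing in a genotype comparison, 8 each way between stages and 5 each way for the interaction, the 5 smallest p where none passed in a direction, and up to 4 members with the smallest p of a described list, passing over clone and predicted names. A few further members are given with their values as examples and were chosen after those were seen. Alternatives covered the filter, normalization, the value standing for a gene, the spread estimate, array weights, the samples in the fit, blocks for replicate number and deposition run, sex, thresholds and leaving out each array. Added after seeing the data were a fit without the 2 arrays of lowest weight (WT replicate 4 and KO replicate 2 of 6 weeks), a fit with neuron, neighbouring cortex and hippocampus, and choroid plexus and ependyma scores as covariates, and a fit with sex and deposition run together.

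Sex was read from Xist and Y-linked genes. There were 2 females and 2 males in WT and 1 female and 2 males in KO at 6 weeks, and 2 females and 3 males in WT and 3 of each in KO at 12 weeks. The arrays of 12 weeks were deposited in 2 runs that each held both genotypes, which may or may not mark a batch; in the first run the WT arrays were female and the KO arrays male, and in the second the reverse. No array dates were used here.

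The steps were tested on simulated data in which 100 genes each were changed by a log2 of 1 or 2 among 16332. For KO against WT at 6 weeks 42 and 96 of them were called, at 12 weeks 56 and 98, for stage in WT 50 and 97, for stage in KO 49 and 98, and for the interaction 17 and 81, with 9, 9, 7, 12 and 5 false calls. The simulated noise was normal and independent between genes, with no outlying array. The real arrays are less regular, so these rates may not carry over to them. Tables were prepared and plots drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.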

Results

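The data are 18 one-colour oligonucleotide arrays of RNA from the caudal corpus callosum, a large white matter tract, of C57BL/6 mice fed a diet with 0.2% cuprizone (CPZ), a copper chelator that kills oligodendrocytes and strips myelin. Mice carried either normal Trem2 alleles (WT) or a knockout of Trem2 (KO), the gene of a myeloid cell surface receptor that signals through the adaptor TYROBP. The labels give 2 stages, 6 and 12 weeks, with 4 WT and 3 KO arrays at 6 weeks and 5 WT and 6 KO arrays at 12 weeks. The labels leave open whether a stage is the age of the mice or the time on CPZ, since sample descriptions speak of mouse age while the treatment protocol gives mice in that age range and several feeding times. No array of mice without CPZ was among the samples used here, so levels are compared between genotypes and between stages and not with normally fed tissue. Values are log2 probe-set signals summarised to genes, and 16332 genes were tested. The number of arrays, and not a read depth, limits the precision. Nothing in the labels says that each array is a separate mouse, so p-values measure the spread between these samples, which may in part be technical.

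Trem2 itself was examined first, because its level checks the genotype labels. At 6 weeks the Trem2 value was 7.29 ± 0.83 (SD, n = 4) in WT and 5.81 ± 0.34 (SD, n = 3) in KO. At 12 weeks it was 7.36 ± 0.48 (SD, n = 5) in WT and 5.27 ± 0.30 (SD, n = 6) in KO. The highest KO array lay below the lowest WT array at both stages, at 6.05 against 6.44 and at 5.59 against 6.83. The log2 difference of KO from WT was −1.49 ± 0.36 (SE) at 6 weeks, 2.80-fold lower, which did not pass over all genes (adjusted p = 0.248). An exact two-sided permutation test gave p = 0.0571 at 6 weeks, where 35 arrangements allow 0.0286 at the smallest. At 12 weeks the difference was −2.09 ± 0.28 (SE), 4.27-fold lower, with adjusted p = 0.00253 and an exact permutation p of 0.00216, the smallest that 462 arrangements can give. The 7 probe sets of Trem2 differed in size of change. At 12 weeks their log2 differences ran from −0.74 to −3.29, and at 6 weeks from 0.16 to −2.89. The probe set with the highest signal was −1.52 and −1.89 from WT at 6 and 12 weeks and still stood at 9.61 and 9.12 in KO. Which exons the knockout removes is not given in the sources used here, so a probe set outside the deleted part would check nothing. The neighbouring family members Treml1 (0.01 and −0.28 at 6 and 12 weeks) and Treml2 (−0.11 and −0.13) did not pass the test, nor did the adaptor Tyrobp (0.73, adjusted p = 0.653, and 0.32, adjusted p = 0.555).

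**Figure D1:**
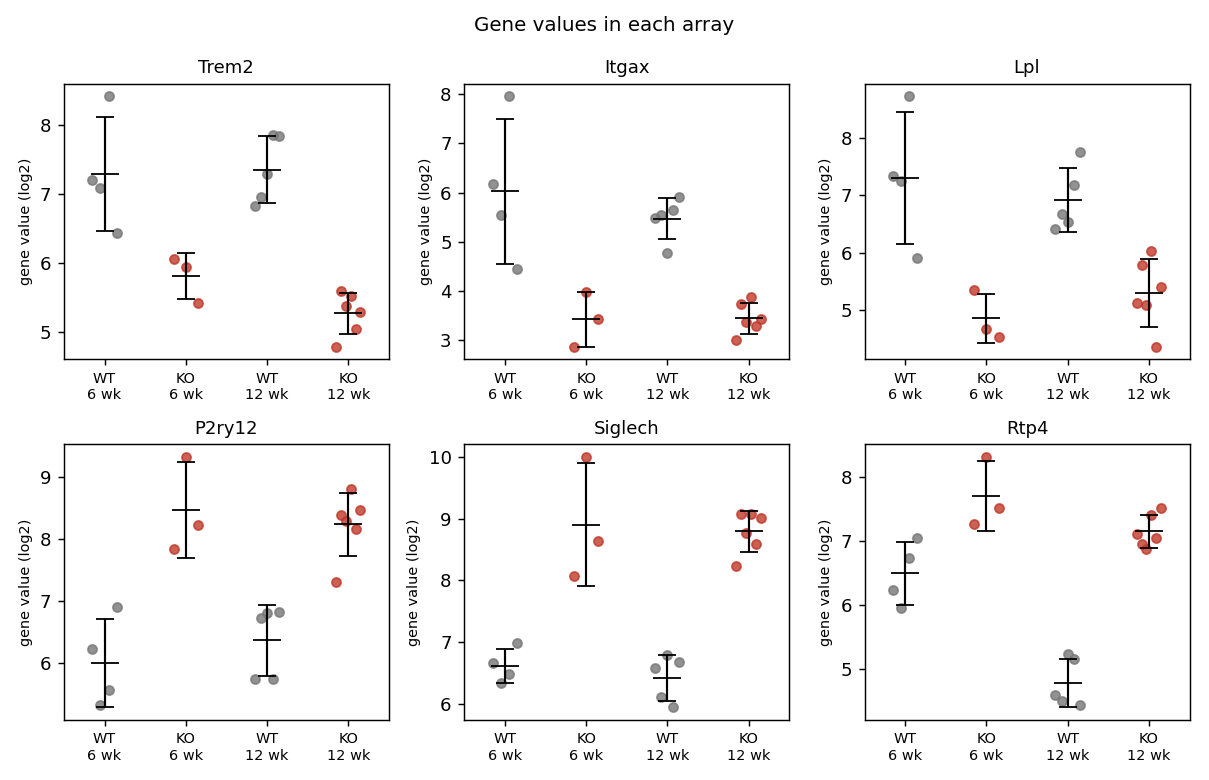
Gene values (log2, vertical axes) of Trem2, Itgax, Lpl, P2ry12, Siglech and Rtp4 in each array of the 4 groups (horizontal axes: WT in grey and KO in red, at 6 and 12 weeks); points are arrays and bars are group mean ± SD. The KO arrays lie below all WT arrays of their stage for Trem2, with 6.05 as the highest KO and 6.44 as the lowest WT value at 6 weeks.

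The comparison of KO with WT at 6 weeks asks how loss of TREM2 alters transcripts in CPZ-exposed white matter. Genes that mark resting microglia were higher in KO. P2ry12, a purinergic receptor of microglial processes, was higher by 2.47 ± 0.42 (log2, SE), which is 5.52-fold, and its neighbour P2ry13 by 2.19 ± 0.31, which is 4.57-fold. Siglech, a sialic acid-binding lectin of microglia, was higher by 2.30 ± 0.34. The crystallin gene Crybb1 (1.75 ± 0.27), Thrsp (1.75 ± 0.27), which acts in lipid synthesis, Ecscr (2.29 ± 0.41), known from endothelium, and Zfp36 (1.18 ± 0.20), which promotes mRNA decay, completed the set. These 7 genes passed, all higher in KO (adjusted p from 0.0113 for P2ry13 to 0.0420 for Ecscr), and no gene passed in the other direction. Genes lower in KO did pass in other settings: 5 lower and 4 higher, 4 of them shared with the 7, without the 2 arrays of lowest weight, 8 lower and 7 higher with tissue scores as covariates, 3 lower and 6 higher without WT replicate 4, and 1 lower with array weights or with the mean of the probe sets. By unadjusted p, 888 genes lay under 0.05, against 816.6 given by chance. Of the genes lower in KO, those with the smallest p were Lpl, the lipoprotein lipase (−2.45 ± 0.49, adjusted p = 0.0883), the integrin gene Itgax (−2.60 ± 0.52, adjusted p = 0.0883), the matrix gene Postn (−2.18 ± 0.47, adjusted p = 0.153), Arpc1a (−0.82 ± 0.19, adjusted p = 0.236) and Trem2. Without WT replicate 4, Itgax KO vs WT at 6 weeks (−3.13) and Lpl KO vs WT at 6 weeks (−2.91) did pass (adjusted p = 0.00791 each). The KO mean of Itgax (3.43) lay near the level of 3.41 under which genes were left out, as did that of Postn. The sizes of these differences are therefore uncertain. The number of genes passing was 0 without WT replicate 1, 2 without WT replicate 2, 11 without WT replicate 3, 1 without KO replicate 2, 4 without KO replicate 3 and 0 in a fit of these 7 arrays alone. Ecscr differed by 0.06 when its brightest probe set stood for the gene, against 2.29 for the median of its probe sets.

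Of the gene lists fixed beforehand, homeostatic microglia had the largest shift at 6 weeks. Its 19 measured members had a median log2 difference of 1.07, 18 were higher in KO, and 3 passed over all genes (P2ry12, P2ry13 and Siglech). Gpr34 (1.93, adjusted p = 0.101) did not pass. Adjusted over the list alone, 15 members rose and 0 fell. The list passed camera (adjusted p = 1.02e-27), and also passed with an estimated correlation (adjusted p = 0.0435). All 3 KO arrays scored above all 4 WT arrays (exact permutation p = 0.0286, the smallest possible; 0.443 after adjustment over 31 lists). The astrocyte list (13 members, median 0.51, adjusted p = 4.53e-09, and adjusted p = 0.0435 with an estimated correlation) was higher with 0 members passing over all genes and 3 adjusted over the list alone, led by the glutamate transporter gene Slc1a2 (1.11, adjusted p = 0.0746). Immediate early genes, which respond within minutes to stimulation or handling, were higher as well (16 members, median 0.62, adjusted p = 6.82e-08, and adjusted p = 0.0435 with an estimated correlation). None of them passed over all genes and 5 did adjusted over the list alone. Ier2 (1.92), Fos (1.60) and Btg2 (1.34) had the smallest p. These 3 lists were the only ones of 31 to pass at 6 weeks with an estimated correlation, and fry called 3. The calls with an estimated correlation lay close to the threshold. Leaving out each of the 18 arrays in turn, 12-week arrays included, the homeostatic list kept its call in 5 cases (adjusted p from 0.0125 to 0.109), the astrocyte list in 3 (0.0125 to 0.180) and the immediate early list in 2 (0.0310 to 0.126). With sex as a covariate they were at adjusted p = 0.0560, 0.0615 and 0.0615.

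KO replicate 2 at 6 weeks stood apart, with Fos at 8.40 against 6.68 and 6.23 in the other KO arrays and with the lowest array weight of all 18 (0.446). Without it the median of the homeostatic list was 0.67 (adjusted p = 0.0551 with an estimated correlation), of the astrocyte list 0.25 (adjusted p = 0.180 with an estimated correlation; 0.82 without KO replicate 1), and of the immediate early list 0.29 (adjusted p = 0.119 with an estimated correlation).

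Other lists passed camera at 6 weeks and lost the call with an estimated correlation. Interferon response genes were higher in 18 of 18 members (median 0.61, adjusted p = 7.06e-12, and adjusted p = 0.0778 with an estimated correlation), with 5 passing adjusted over the list alone and 0 over all genes. Ifit3 (1.10) and Rtp4 (1.21) had the smallest p. Without KO replicate 2 this median was 0.30, and without KO replicate 1 it was 0.97. Pan-myeloid genes had a median of 0.88 (20 members, adjusted p = 1.94e-10, and adjusted p = 0.265 with an estimated correlation), with Itgam at 1.60 and Aif1 at 1.36, 9 passing adjusted over the list alone, and a median of 0.41 without KO replicate 2. Without the 2 arrays of lowest weight that list was not called (median 0.34, adjusted p = 0.468). Disease-associated microglia genes went both ways. Of 28 members 16 were lower and 12 higher, the median was −0.10 and the mean −0.43, and camera placed the list lower (adjusted p = 0.0139, and adjusted p = 0.583 with an estimated correlation). The 4 that passed adjusted over the list alone were all lower in KO: Itgax and Lpl, Cybb (−2.35), the catalytic subunit of the phagocyte NADPH oxidase, and Spp1 (−1.87), which encodes osteopontin, while 0 passed over all genes. That list was not called without WT replicate 3 (adjusted p = 0.676), KO replicate 1 (adjusted p = 0.633) or KO replicate 3 (adjusted p = 0.220), where the medians were −0.03, 0.01 and −0.01. It was −0.05, −0.22 and −0.33 without WT replicates 1 and 2 and KO replicate 2, −0.38 without the 2 arrays of lowest weight and −0.41 with tissue scores. Genes of mature oligodendrocytes and myelin had a median of −0.55 (20 members, 18 lower, 0 passing either way of adjustment; adjusted p = 4.33e-04, and adjusted p = 0.571 with an estimated correlation). Without WT replicate 4 that median was −0.22 (adjusted p = 0.241) and without KO replicate 3 it was −0.01 (adjusted p = 0.516), and it was −0.89, −0.34 and −1.01 without WT replicates 1 and 3 and KO replicate 2. The myelin median was 0.73 in males (19 of 20 members higher in KO, 2 arrays against 2) and −2.34 in females (0 of 20 higher, 1 KO array against 2). The scores did not follow sex: male KO replicate 2 (1.24) lay nearest the female WT replicates 3 and 4 (1.52 and 2.01). Female KO replicate 3 was at −0.46. In males and females the medians at 6 weeks were 1.51 and 0.63 for homeostatic microglia and 1.07 and 0.27 for interferon response genes. They were 1.22 and 0.26 for pan-myeloid and −0.03 and −0.57 for disease-associated genes. The female values rest on 1 KO array. No difference between sexes was tested.

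At 12 weeks the same comparison gave 72 genes, 60 higher and 12 lower in KO. Siglech was higher by 2.38 ± 0.27 (log2, SE; adjusted p = 2.84e-04), and the interferon-induced gene Rtp4 by 2.37 ± 0.23, or 5.18-fold (adjusted p = 4.18e-05). Other microglial genes were Fcrls (2.13 ± 0.41), P2ry12 (1.87 ± 0.33), P2ry13 (1.70 ± 0.24) and Itgam (1.76 ± 0.27), which encodes the integrin CD11b. Ecscr (1.94 ± 0.32), Cnmd (1.81 ± 0.34), which encodes chondromodulin, and the chemokine genes Cxcl5 (1.81 ± 0.34) and Cxcl10 (1.69 ± 0.34) complete the 10 largest rises. Of the genes that fell, Trem2 was followed by Atp6v0d2 (−2.08 ± 0.40), a subunit of the vacuolar proton pump found in macrophages and osteoclasts, and Itgax (−2.02 ± 0.41).

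The other falls at 12 weeks among the 10 largest were those of Moxd1 (−1.60 ± 0.33), Ostn (−1.48 ± 0.28), which encodes osteocrin, Grpr (−1.18 ± 0.25), the receptor of gastrin-releasing peptide, the formin gene Fhod3 (−0.97 ± 0.21), Cyp2d40 (−0.93 ± 0.21), Erfe (−0.92 ± 0.18), which encodes erythroferrone, and Zfp454 (−0.90 ± 0.17). Adjusted p in these 20 genes was at most 0.0471 (Fhod3 and Cyp2d40). The KO means of Grpr (3.05), Itgax (3.45) and Atp6v0d2 (3.53) lay under or near the level of 3.41 below which genes were left out. The sizes of their differences are therefore uncertain. The 12 falls depended on dim genes and on single arrays: 2 genes were lower and 67 higher with a stricter filter on dim genes, and 2 were lower without any 1 of WT replicates 1, 3, 4 and 5 or KO replicates 2, 3 and 6. The rises depended on single arrays as well, with 13 to 22 genes higher in those fits. With the brightest probe set 55 were higher and 6 lower, and 27 of the 72 were shared. By unadjusted p, 1811 genes lay under 0.05 against 816.6 given by chance. In the separate arrays of 6 weeks, 63 of these 72 genes had the same direction in males and 59 in females, with sex read from Xist and Y-linked genes. With its brightest probe set, Ecscr was at −0.33 (adjusted p = 0.445), Erfe at 0.01 (adjusted p = 0.980) and Rtp4 at 1.10 (adjusted p = 0.112). The number of genes changed KO vs WT at 12 weeks was 45 after quantile normalization, 20 with a block for replicate number, 191 with array weights and 234 in a fit of these 11 arrays alone. It was 17, 15, 16 and 20 without WT replicates 1, 3, 4 and 5, it was 19, 24, 31, 26 and 15 without KO replicates 2 to 6, and it was 122 and 130 without the 6-week arrays WT replicate 4 and KO replicate 2.

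Homeostatic microglia genes were higher in KO at 12 weeks in 19 of 19 members (median 1.02), with 8 passing over all genes and 18 adjusted over the list alone. Siglech, P2ry13, P2ry12 and Gpr34 (1.66) had the smallest p. Every KO array scored above every WT array (0.54 against −0.65 on average, exact permutation p = 0.00216, adjusted over 31 lists 0.0192). The list passed camera (adjusted p = 1.27e-24) and fry (adjusted p = 0.00195), and missed the threshold in camera (adjusted p = 0.0530 with an estimated correlation). Interferon response genes were higher in 18 of 18 members (median 0.86, adjusted p = 1.83e-16, and adjusted p = 0.0530 with an estimated correlation), with 5 passing over all genes and 11 adjusted over the list alone. Among these were Rtp4, Ifit3 (1.30), Ifit1 (1.62) and Bst2 (1.38). The medians of these 2 lists were 1.00 and 0.70 in the first deposition run, 1.17 and 1.04 in the second, 0.99 and 0.77 in males and 1.16 and 0.91 in females. Within a run KO and WT arrays differed in sex, and within a sex they differed in run, so neither division removes the other.

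Pan-myeloid genes were higher at 12 weeks (median 0.92, 17 of 20 members; adjusted p = 1.29e-10, and adjusted p = 0.318 with an estimated correlation), with Itgam and Laptm5 (1.54) passing over all genes and 12 adjusted over the list alone. Complement genes were higher in 12 of 12 members (median 0.67, adjusted p = 3.21e-07, and adjusted p = 0.145 with an estimated correlation), with Itgam, a complement receptor subunit, passing over all genes and 5 adjusted over the list alone. C1qb stood at 1.51 and C4b at 1.07. Astrocyte genes had a median of 0.47 (adjusted p = 2.17e-07, and adjusted p = 0.0594 with an estimated correlation), with the bicarbonate cotransporter gene Slc4a4 (1.01) passing over all genes and 7 adjusted over the list alone. Genes of blood monocytes and border macrophages had a median of 0.47 (10 members, adjusted p = 0.00174, and adjusted p = 0.109 with an estimated correlation). In that list the scavenger receptor gene Stab1 (1.00) passed over all genes and 3 members did adjusted over the list alone, and the median was 0.28 without WT replicate 2, 0.80 without WT replicate 4, 0.14 in males and 0.92 in females. Lysosome genes had a median of 0.40 (20 members, adjusted p = 0.00153, and adjusted p = 0.549 with an estimated correlation), in which Atp6v0d2 fell while 2 rose adjusted over the list alone, and the median was 0.10 in males and 0.76 in females. The male and female medians compare KO and WT arrays of different deposition runs.

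The disease-associated microglia list did not pass at 12 weeks (28 members, median 0.07, mean −0.12, adjusted p = 0.904). Itgax fell over all genes. Adjusted over the list alone, 4 rose and 4 fell, among them Timp2 (0.99), Lpl (−1.61) and Cybb (−2.14), none of which passed over all genes. Genes of mature oligodendrocytes and myelin did not pass either (median 0.27, adjusted p = 0.578), with 0.79 in the first deposition run and −0.25 in the second. Choroid plexus and ependyma genes, from tissue that lines the ventricle beside the corpus callosum, had a median of 0.82 (14 members, adjusted p = 0.00480, and adjusted p = 0.549 with an estimated correlation). None passed over all genes and Tmem212 (2.20) alone did adjusted over the list alone. The choroid plexus median was −0.10 in males, 1.75 in females and 0.40 without KO replicate 6. Within each sex the KO and WT arrays came from different deposition runs, and within each run from different sexes. Sex and run can therefore not be told apart in the choroid plexus and myelin medians.

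**Figure D2:**
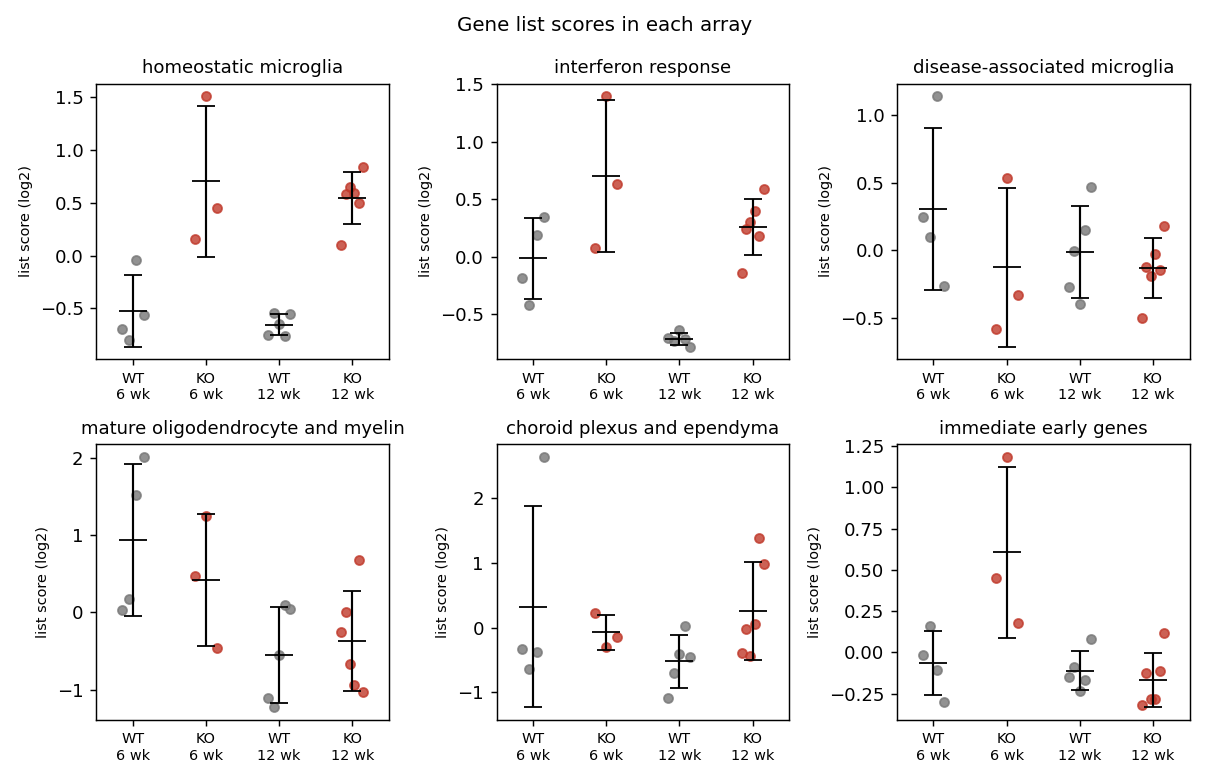
List scores (mean over a list's genes of the log2 value minus its mean over all arrays, vertical axes) of 6 gene lists in each array of the 4 groups (horizontal axes: WT in grey and KO in red); points are arrays and bars are group mean ± SD. At 12 weeks the homeostatic microglia score averaged 0.54 in KO and −0.65 in WT with no overlap, and 1 WT array at 6 weeks reached 2.64 for choroid plexus and ependyma.

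The genotype differences at both stages were set side by side, since the 6-week and 12-week arrays are separate. Of the 7 genes higher in KO at 6 weeks, 6 also passed at 12 weeks, against 0.0257 for independent lists. Both comparisons share 1 estimate of the spread per gene, so more overlap than for independent lists can arise from that alone. Of the 60 genes higher in KO at 12 weeks 52 were higher at 6 weeks too, with a median log2 difference of 1.36 at 12 and 0.88 at 6 weeks. Of the 12 genes lower at 12 weeks 9 were lower at 6 weeks, with medians of −1.08 and −0.18. Across all genes, which are not independent replicates, 54.1% had the same sign at both stages. Their log2 differences had r = 0.212 and rho = 0.135. Siglech, P2ry12 and P2ry13 lay at the upper end of both comparisons, and Itgax, Lpl and Cybb were the lowest members of the disease-associated list in both.

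**Figure D3:**
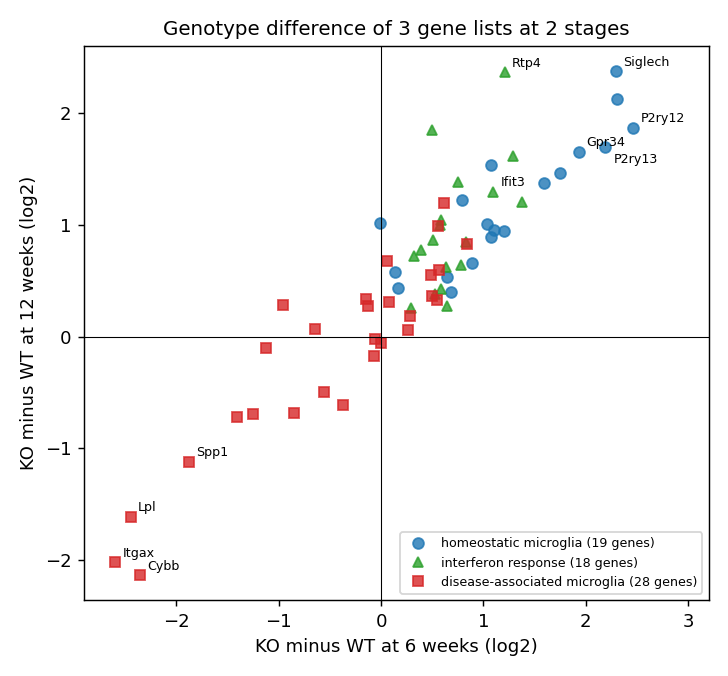
Log2 difference of KO from WT at 6 weeks (horizontal axis) and at 12 weeks (vertical axis) for the members of 3 gene lists; each point is a gene and the lines mark 0. Siglech lies at 2.30 and 2.38, and Itgax at −2.60 and −2.02.

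The comparison of 12 with 6 weeks in WT shows how transcripts differ between stages with TREM2 present. Prox1, a transcription factor of dentate gyrus granule neurons and of lymphatic endothelium, was lower at 12 weeks by −2.07 ± 0.29 (log2, SE; adjusted p = 0.0121). Rtp4 was lower by −1.71 ± 0.26 (adjusted p = 0.0150), and Tbc1d8b, which encodes a Rab GTPase-activating protein, by −1.64 ± 0.25 (adjusted p = 0.0166). The mean of Tbc1d8b at 12 weeks was 3.40, near the filter level, so the size of its fall is uncertain. These 3 genes were all that passed, none of them higher at 12 weeks. The genes with higher values and the smallest p were Moxd1 (2.00, adjusted p = 0.0629), the neuropeptide gene Vip (1.18, adjusted p = 0.0657), Ostn (1.68, adjusted p = 0.0657), Plcl2 (1.08, adjusted p = 0.0824) and Sdr39u1 (1.10, adjusted p = 0.198), and none of them passed. By unadjusted p, 1384 genes lay under 0.05. The WT arrays of 12 weeks also serve in the genotype comparison of that stage, so values of Rtp4, Moxd1 and Ostn in both comparisons share their chance errors. None of the 3 passed when the brightest probe set stood for each gene (Prox1 −1.79, Rtp4 −0.98, Tbc1d8b −0.33). The number passing was 1 without WT 6-week replicate 2 or WT 12-week replicate 2, 6 without WT 12-week replicate 4, 5 without KO 12-week replicate 4, 8 with arrays centred on their medians, 7 with sex as a covariate and 1 with the deposition run as a block.

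Mature oligodendrocyte and myelin genes were lower at 12 than at 6 weeks in WT in 20 of 20 members. Their median was −1.63, and Cldn11 (−2.01), Ppp1r14a (−2.07), Ugt8a (−1.95) and Plekhh1 (−1.63) had the smallest p. No member passed over all genes, and 17 fell adjusted over the list alone. The list score was 0.93 ± 0.98 (SD) at 6 weeks and −0.55 ± 0.62 at 12 weeks (exact permutation p = 0.0238, or 0.148 adjusted over 31 lists). The list passed camera (adjusted p = 1.57e-20), and lost the call with adjusted p = 0.214 with an estimated correlation. With scores for neuronal, cortical and hippocampal, and choroid plexus content as covariates, chosen after the data had been seen, its median was −1.04. WT 6-week replicates 3 and 4, both female, scored 1.52 and 2.01, against 0.03 and 0.18 in the 2 males of that stage. The median was −3.14 in females (0 of 20 members higher) and −0.22 in males (5 of 20 higher). At 12 weeks the WT females are the first deposition run and the WT males the second, so sex and run cannot be told apart here. Whether the sexes differ was not tested.

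Interferon response genes were lower at 12 weeks in WT in 18 of 18 members (median −0.57, adjusted p = 7.40e-10, and adjusted p = 0.214 with an estimated correlation). Rtp4 fell over all genes and 5 fell adjusted over the list alone, and Oas1a stood at −1.36 and Bst2 at −1.05. All 5 arrays of 12 weeks scored below all 4 of 6 weeks (exact permutation p = 0.00794, the smallest possible, or 0.123 adjusted over 31 lists). Neutrophil genes were higher (5 members, median 0.46, adjusted p = 0.00224, and adjusted p = 0.120 with an estimated correlation), with the calgranulin genes S100a9 (1.79) and S100a8 (1.21) passing adjusted over the list alone and 0 over all genes. That median was 0.27 without WT 12-week replicate 1. Reactive astrocyte genes were lower (16 members, median −0.23, adjusted p = 0.00224, and adjusted p = 0.512 with an estimated correlation), with Cxcl10 (−1.82), S1pr3 (−1.16) and Lcn2 (−1.63) falling adjusted over the list alone. Without WT 6-week replicate 3 that list was not called (median 0.03, adjusted p = 0.357), and without WT 6-week replicate 4 its median was −0.37. Neuron genes (median 0.37, adjusted p = 0.00772, and adjusted p = 0.512 with an estimated correlation) and those of neighbouring cortex and hippocampus (median 0.52, adjusted p = 0.0151, and adjusted p = 0.512 with an estimated correlation) were higher, and choroid plexus and ependyma genes lower (median −0.75, adjusted p = 0.00377, and adjusted p = 0.512 with an estimated correlation). The neuron list was not called without WT 6-week replicate 3 (adjusted p = 0.273) or 4 (adjusted p = 0.251), with medians of 0.22 and 0.11 and of 0.60 without WT 6-week replicate 1, nor the cortex and hippocampus list without WT 6-week replicate 3 (median 0.47, adjusted p = 0.0891) or 4 (median 0.15, adjusted p = 0.558). The choroid plexus list was not called without WT 6-week replicate 4 (median −0.10, adjusted p = 0.749). Medians in males and females were −0.31 and −0.87 for interferon response, 0.02 and −0.53 for reactive astrocyte, −0.07 and 0.80 for neuron, 0.07 and 0.98 for cortex and hippocampus, and 0.21 and −1.85 for choroid plexus genes. These medians also divide the WT arrays of 12 weeks by deposition run. In all, 17 of 31 lists passed camera and 0 passed with an estimated correlation.

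The comparison of 12 with 6 weeks in KO asks the same without TREM2. Zfp36 fell by 1.51 ± 0.19 (log2, SE; adjusted p = 0.00174), and it was the only gene to pass, with 1226 under an unadjusted p of 0.05. The same KO arrays of 6 weeks enter the genotype comparison of that stage, in which Zfp36 was higher. Genes with higher values and the smallest p did not pass: the calcium-binding protein gene Necab2 (1.57, adjusted p = 0.127), the sodium channel gene Scnn1a (1.42), Rpl14 (0.82), Cenpk (1.52, from a mean as low as 2.57 at 6 weeks) and Pdcd6 (0.86), the last 4 with adjusted p = 0.205 each. The value of Zfp36 12 vs 6 weeks in KO missed the threshold with WT replicate 4 and KO replicate 2 of 6 weeks left out (−1.37, adjusted p = 0.0749) and with tissue scores as covariates (−1.35, adjusted p = 0.0504), settings chosen after the data had been seen, and in a fit of these 9 arrays alone (adjusted p = 0.0549). Without KO 6-week replicate 3, 5 genes passed.

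Immediate early genes were lower at 12 than at 6 weeks in KO (median −0.68, 13 of 16 members; adjusted p = 2.16e-09, and adjusted p = 0.0501 with an estimated correlation). No member passed over all genes and 8 fell adjusted over the list alone, with Fos (−1.75), Egr1 (−1.67), Ier2 (−1.71) and Btg2 (−1.26) at the smallest p. All 6 arrays of 12 weeks scored below the 3 of 6 weeks (exact permutation p = 0.0119, the smallest possible, or 0.184 adjusted over 31 lists), and without KO 6-week replicate 2 the median was −0.44. Genes of mitochondrial oxidative phosphorylation were higher (18 members, median 0.39, adjusted p = 1.93e-07, and adjusted p = 0.163 with an estimated correlation), with Cox7a2 (0.63), Ndufa4 (0.70), Atp5o (0.60) and Uqcrc1 (0.56) passing adjusted over the list alone and 0 over all genes. Mature oligodendrocyte and myelin genes were lower in 20 of 20 members (median −0.82, adjusted p = 1.60e-07, and adjusted p = 0.497 with an estimated correlation), with 0 passing either way of adjustment. Their median was −0.34 with tissue scores, −0.40 without KO 6-week replicate 2, −1.24 without KO 6-week replicate 3, which is the only female KO array of 6 weeks, −1.20 in males and 0.06 in females. Neuron genes (median 0.56, adjusted p = 4.35e-05, and adjusted p = 0.497 with an estimated correlation) and interferon response genes (median −0.42, adjusted p = 2.99e-05, and adjusted p = 0.497 with an estimated correlation) passed camera but not without KO 6-week replicate 2, where the medians were −0.02 and −0.09. Without KO 6-week replicate 3 the neuron median was 0.84, and without KO 6-week replicate 1 the interferon median was −0.73. With tissue scores the interferon list was not called either (median −0.13, adjusted p = 0.149). In males and females the neuron medians were 0.88 and −0.04 and the interferon medians −0.57 and −0.23. At 12 weeks the KO males are the first deposition run and the KO females the second, so sex and run cannot be told apart in these medians.

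Whether the genotype difference itself changed between stages was tested as an interaction. No gene passed in limma (0 of 16332, smallest adjusted p = 0.414), and 851 lay under an unadjusted p of 0.05 against 816.6 given by chance. Tbc1d8b (1.94), Rerg (1.97), Rwdd3 (2.30), Scnn1a (1.92) and Zfp882 (1.33) had the smallest p among positive interactions. By group means, each of them was lower in KO at 6 weeks and higher in KO at 12 weeks. Zfp36 (−1.10), Cyp2d40 (−1.38), Tex48 (−1.26), Trnau1ap (−1.12) and Egr1 (−1.89) had the smallest p among negative interactions. Zfp36 was higher in KO at both stages by group means, and the others turned from higher at 6 weeks to lower at 12 weeks. For Trem2 the interaction was −0.61 ± 0.46 (SE, adjusted p = 0.963). The homeostatic microglia list (median −0.17, adjusted p = 0.777), the interferon response list (0.27, adjusted p = 0.165) and the disease-associated list (0.22, adjusted p = 0.0874) did not pass. The difference in calls between stages is therefore not shown to be a difference in effect for these lists. Immediate early genes had the smallest p of the lists (median −0.52, adjusted p = 7.16e-06, and adjusted p = 0.124 with an estimated correlation), and 0 of 31 lists passed with an estimated correlation.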

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

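The rules that singled out the values below were fixed beforehand, and only the values without single arrays, within each sex, with tissue scores and without the 2 arrays of lowest weight were looked up after the results were seen. Of 231 groups of values examined for 1 array far from the others, 7 held one, where chance gives about 1 in 20. Rwdd3 stood at 5.94 in WT 6-week replicate 1, with 4.39 as the nearest other array. In WT 6-week replicate 3 the scores for antigen presentation (0.73, nearest −0.07), phagocytic receptors (0.59, nearest −0.10) and reactive astrocytes (0.85, nearest −0.06) stood above the other 3 arrays. In WT 6-week replicate 4 the choroid plexus and ependyma score was 2.64 (nearest −0.33). The integrated stress response score was −0.24 in WT 6-week replicate 2 (nearest 0.11), and the T cell score was −0.35 in KO 12-week replicate 1 (nearest 0). All of these arrays are in the fit of 18 arrays, and values without one of them are named as such.

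In camera, 9 of 31 lists differed between stages in their genotype difference, and 0 did with an estimated correlation or in fry. Immediate early genes had a median interaction of −0.52 (13 of 16 members lower, adjusted p = 7.16e-06, and adjusted p = 0.124 with an estimated correlation), with Egr1 at −1.89, Ier2 at −1.73 and Fos at −1.48. Neutrophil genes were at −0.61 (5 of 5 lower, adjusted p = 0.00484, and adjusted p = 0.124 with an estimated correlation). Choroid plexus and ependyma genes were at 0.99 (13 of 14 higher, adjusted p = 0.00278, and adjusted p = 0.683 with an estimated correlation), and at 0.45 without WT 6-week replicate 4 (adjusted p = 0.342). Mature oligodendrocyte and myelin genes were at 0.75 (19 of 20 higher, adjusted p = 0.00278, and adjusted p = 0.926 with an estimated correlation). Their median was 0.43 without WT 6-week replicate 4 (adjusted p = 0.176) and 0.31 without KO 6-week replicate 3 (adjusted p = 0.415). Cholesterol synthesis genes were at 0.45 (12 of 15 higher, adjusted p = 0.00384, and adjusted p = 0.539 with an estimated correlation), and at 0.20 and 0.26 without WT 6-week replicate 4 and WT 12-week replicate 1. Genes of the integrated stress response were at −0.18 (13 of 17 lower, adjusted p = 0.00702, and adjusted p = 0.615 with an estimated correlation), and at −0.04 without KO 6-week replicate 2 (adjusted p = 0.566). Without WT 6-week replicate 2 that call was lost (adjusted p = 0.0555). The stress response median was −0.38 without KO 6-week replicate 3, −0.11 and −0.28 without WT 12-week replicates 2 and 4, and −0.30 without KO 12-week replicate 4 or 6. Oxidative phosphorylation genes were at 0.27 (14 of 18 higher, adjusted p = 0.00938, and adjusted p = 0.572 with an estimated correlation). That call was lost without WT 6-week replicate 1 (adjusted p = 0.0947) or KO 6-week replicate 2 (adjusted p = 0.0705). Cell cycle genes were at −0.32 (11 of 15 lower, adjusted p = 0.0215, and adjusted p = 0.539 with an estimated correlation), and antigen presentation genes at 0.36 (13 of 15 higher, adjusted p = 0.0354, and adjusted p = 0.866 with an estimated correlation). The cell cycle call was lost without WT 6-week replicate 1 (−0.21, adjusted p = 0.210), KO 6-week replicate 2 (−0.08, adjusted p = 0.0558) or WT 12-week replicate 2 (−0.13, adjusted p = 0.159). The antigen presentation median was 0.69 without KO 6-week replicate 2, and the call was lost without WT 6-week replicate 3 (0.19, adjusted p = 0.326), KO 6-week replicates 1 (0.13, adjusted p = 0.566) and 3 (0.31, adjusted p = 0.0945), WT 12-week replicate 3 (0.23, adjusted p = 0.223), and KO 12-week replicates 4 (0.28, adjusted p = 0.155) and 6 (0.33, adjusted p = 0.0610). With tissue scores the calls of cell cycle (−0.23, adjusted p = 0.0754), cholesterol synthesis (0.27, adjusted p = 0.0580), stress response (−0.11, adjusted p = 0.156) and oxidative phosphorylation genes (0.21, adjusted p = 0.0795) were lost. The choroid plexus list (−0.23, adjusted p = 0.888) cannot be judged in that fit, since its own score is a covariate. The call of cell cycle was also lost after quantile normalization (−0.29, adjusted p = 0.0956), as was that of antigen presentation with sex as a covariate (0.28, adjusted p = 0.0758). Without the 2 arrays of lowest weight the calls of cholesterol synthesis (adjusted p = 0.102), choroid plexus (0.596), stress response (0.472) and oxidative phosphorylation (0.105) were lost. Within males and females the medians were −0.91 and 3.00 for myelin, −0.47 and 3.13 for choroid plexus, −0.70 and 0.38 for stress response, 0.46 and −0.11 for oxidative phosphorylation, −0.01 and 0.63 for antigen presentation, 0.10 and 0.79 for cholesterol synthesis, −0.33 and −0.12 for cell cycle, −0.14 and −1.03 for neutrophil and −0.44 and −0.50 for immediate early genes, with 1 female KO array at 6 weeks. Within each genotype at 12 weeks, sex is the same division as deposition run, so these medians belong to run as much as to sex. Of 100 splits of the arrays, 60 gave as many lists for the interaction as the 9 found, and the highest other split gave 21.

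Probe sets with no gene symbol or with several were tested apart from the genes, 23581 in all after the filter. Of these, 2 passed higher in KO at 6 weeks (smallest adjusted p = 0.0202) and 1 was lower at 12 than at 6 weeks in KO (adjusted p = 0.00288), and none passed in the other comparisons in limma.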

How the results depend on the processing

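The fits without the 2 arrays of lowest weight, with tissue scores and with sex and deposition run together were chosen only after the results were seen. The numbers of genes passing, 7 and 72 between genotypes at 6 and 12 weeks, 3 and 1 between stages in WT and KO and 0 for the interaction, and of lists, 17, 16, 17, 11 and 9, are compared below with those of other settings where they moved by over 1.5 times or a call changed. Siglech and P2ry13 at 12 weeks passed in every setting run. The fit for 2 groups alone was not run for the interaction.

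Quantile normalization gave 45 genes between genotypes at 12 weeks, and centring arrays on their medians gave 8 between stages in WT (3 higher and 5 lower). With the brightest probe set per gene, 1 gene passed between stages in WT and 3 in KO, with 7 lists in KO, and at 12 weeks Ecscr (−0.33) and Erfe (0.014) reversed against WT. With the mean of the probe sets, 5 genes passed between stages in WT and 3 in KO, with 17 lists in KO. Array weights gave 191 genes between genotypes at 12 weeks. A block for replicate number gave 0 and 20 genes between genotypes at 6 and 12 weeks and 0 and 2 between stages in WT and KO. Whether the numbers pair these arrays is unclear. Of 8 pairs with the same number in a stage, 1 had a correlation over 0.1 (from −0.359 to 0.241), while 10 arrays correlated best with their own number. Most of these 10 were arrays of 12 weeks, where pairs of replicates 1 to 5 had r = 0.097, 0.071, 0.024, 0.098 and 0.095. At 6 weeks the pairs had r = 0.241, −0.359 and −0.197. A pairing at 12 weeks is therefore possible, and the main fit leaves it out. The deposition run as a block gave 1 gene between stages in WT, sex as a covariate 7, and both together 0, with 4 between genotypes at 6 weeks.

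Without the 2 arrays of lowest weight, 9 genes passed between genotypes at 6 weeks (4 higher and 5 lower, 4 shared with the 7), 217 genes passed between genotypes at 12 weeks and 0 between stages in KO, with 6 lists in KO and 15 for the interaction. With tissue scores, 15 genes passed between genotypes at 6 weeks (7 higher and 8 lower), 7 and 0 between stages in WT and KO and 2 for the interaction, with 10 lists between stages in WT. In that fit the neuron, cortex and hippocampus, and choroid plexus lists lose their shift by construction, which lowers the number of lists. Fits of 2 groups alone gave 0 and 234 genes between genotypes at 6 and 12 weeks and 1 and 0 between stages in WT and KO. By an unadjusted p under 0.05 with a fold of 1.5, genes changed KO vs WT at 6 weeks numbered 666, genes changed KO vs WT at 12 weeks 879, genes changed 12 vs 6 weeks in WT 817, genes changed 12 vs 6 weeks in KO 734, and genes with a genotype by stage interaction 788. Camera with an estimated correlation called 3, 0, 0, 0 and 0 lists and fry 3, 6, 1, 2 and 0.

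Leaving out 1 array changed the number of genes between genotypes at 6 weeks to 0, 2 and 11 without WT 6-week replicates 1, 2 and 3, and to 1 and 4 without KO 6-week replicates 2 and 3. At 12 weeks it was 122 and 130 without WT 6-week replicate 4 and KO 6-week replicate 2, 17, 15, 16 and 20 without WT replicates 1, 3, 4 and 5, and 19, 24, 31, 26 and 15 without KO replicates 2 to 6. Between stages in WT it was 1 without WT 6-week replicate 2 or WT 12-week replicate 2, 6 without WT 12-week replicate 4 and 5 without KO 12-week replicate 4, and in KO it was 5 without KO 6-week replicate 3. Lists between stages in WT numbered 6 without WT 6-week replicate 3. In KO they numbered 17, 6 and 17 without KO 6-week replicates 1, 2 and 3, and for the interaction 16 without KO 6-week replicate 2.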

Other observations

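The tests of tissue scores, of homeostatic against pan-myeloid genes and of dentate gyrus markers were chosen only after the results were seen. For the tissue scores and the dentate markers the prediction was set before that test was run. The requirement that a value clear its bound by more than its spread was added after the values of the tests were seen. Genes of chemokines and antigen presentation were placed higher in KO at 12 weeks by camera alone. The cytokine and chemokine list had a median of 0.27 (12 of 19 members higher, adjusted p = 0.0181, and adjusted p = 0.462 with an estimated correlation), with Cxcl10 passing over all genes. Adjusted over the list alone, 5 rose and 1 fell, with Cxcl9 at 2.23, Ccl12 at 1.74 and Il1b at −0.66. The list was not called without WT replicate 3 (median 0.12, adjusted p = 0.224) or KO replicate 4 (0.29, adjusted p = 0.0595), and its median was 0.18 and 0.45 without WT replicates 1 and 5, 0.11 and 0.29 in the 2 deposition runs, and 0.21 and 0.47 in males and females. The antigen presentation list had a median of 0.23 (10 of 15 higher, adjusted p = 0.0234, and adjusted p = 0.549 with an estimated correlation), with the class I gene H2-D1 (1.53) passing over all genes, and a median of 0.06 without WT replicate 3 (adjusted p = 0.254). Without KO replicate 4 its adjusted p was 0.121, and its median was 0.34 without WT replicate 5 and 0.10 without KO replicate 6. It was −0.06 in the first deposition run (7 of 15 higher) and 0.45 in the second (13 of 15). Genes of the integrated stress response were lower (median −0.27, 12 of 17 members, adjusted p = 0.00176, and adjusted p = 0.389 with an estimated correlation), with Cdkn1a (−1.26), Sesn2 (−0.84) and Gdf15 (−0.66) falling adjusted over the list alone and 0 over all genes. That median was −0.54 and −0.12 in the 2 runs. In each run KO and WT arrays differed in sex, and in each sex they differed in run. Neutrophil genes were lower (median −0.44, 4 of 5 members, adjusted p = 0.00319, and adjusted p = 0.0594 with an estimated correlation), with S100a9 at −0.92, Camp at −0.54 and Ela2 at −0.44.

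At 6 weeks genes of blood monocytes and border macrophages were higher in KO (median 0.42, 7 of 10 members, adjusted p = 0.00207, and adjusted p = 0.129 with an estimated correlation), with the mannose receptor gene Mrc1 (1.16), F13a1 (1.00), Stab1 (0.85) and Plac8 (0.60) passing adjusted over the list alone and 0 over all genes. That list was not called with tissue scores (median 0.30, adjusted p = 0.0870). Neuron genes had a median of −0.28 at 6 weeks (15 of 16 lower, adjusted p = 0.00780, and adjusted p = 0.571 with an estimated correlation), and the call was lost without WT replicates 1 (−0.08, adjusted p = 0.278) and 2 (−0.11, adjusted p = 0.224) and KO replicate 2 (0.22, adjusted p = 0.147). Their median was −0.47 and −0.53 without WT replicates 3 and 4, and −0.44 and −0.57 without KO replicates 1 and 3. The neuron median was −1.17 in males (1 of 16 higher) and 0.86 in females (15 of 16 higher, 1 KO array). Single arrays weigh heavily here. Of the male KO arrays, replicate 2 scored −1.33 and replicate 1 scored −0.04. The female WT replicates 3 and 4 scored −0.51 and −0.70, against 0.17 in the female KO array. No difference between sexes was tested. Of lists too small to test, the B cell genes Ighm (−0.20 at 6 and 1.22 at 12 weeks), Cd79b (0.63 and −0.09) and Pax5 (0.18 and −0.28) did not pass.

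The homeostatic microglia list was higher in KO at both stages, and 3 explanations other than TREM2 itself were tested. Different amounts of neighbouring tissue in the dissections could not be ruled out: with tissue scores as covariates the median was 0.76 at 6 weeks and 1.06 at 12 weeks, and the lower ratio to the value without them, 0.704, ranged from 0.432 to 1.05 without 1 array. This was first read as excluded and became open when the spread was required. Sex is an unlikely source, since with sex as a covariate the medians were 1.10 and 0.99 and the lower ratio was 0.970 (0.926 to 1 without 1 array), although the numbers of genes passing with that covariate had been seen when the prediction was set. For a general rise of myeloid transcripts, the homeostatic score less the pan-myeloid score was compared. It was higher in KO by 0.54 at 6 weeks and 0.43 at 12 weeks (exact permutation p = 0.00538 within stages, with 0.143 at 6 and 0.00216 at 12 weeks). Such a rise is thus unlikely to be all of the score difference at 12 weeks, and it stays open at 6 weeks. The scores are means, and the medians of the 2 full lists lay closer, at 1.07 and 0.88 at 6 weeks and 1.02 and 0.92 at 12 weeks.

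The fall of Prox1 in WT, from 7.76 at 6 weeks to 5.69 at 12 weeks, may come from less dentate gyrus tissue in the 12-week dissections. The other 10 dentate markers, tested after the fall of Prox1 was seen, had a median of −0.40. The bound was set before this test was run, as a share of the Prox1 value. The median lay nearer to it than the SE of the mean over markers (0.171), the only spread computed. The score of these markers did not differ (exact permutation p = 0.278). The prediction had counted such a p against the explanation, but a missed p shows no absence, so it stays open. Dsp was at −1.39, Dock10 at −1.05 and Calb1 at 0.15. A change in Prox1 within cells is the other candidate, and no value here separates the 2.

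DNA of another strain may flank the targeted gene in knockout mice and alter genes near Trem2. Of the 80 nearest tested genes 2 changed the same way at both stages by unadjusted p, or 2.5%, against a median of 1.25% in 1000 windows elsewhere (percentile 83.8, with 3.75% as the 95th). At 12 weeks alone 7 of them, or 8.75%, had an unadjusted p under 0.05, against a median of 11.25%, and 0 passed in limma. With 2 genes the test cannot tell a small effect of flanking DNA from none, a reading that also moved from excluded to open when the spread was required.

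Arrays were also split in other ways into groups of the same sizes, with the real split counted. At most 100 splits were drawn per comparison, so where more exist the highest other count holds for those drawn. Between genotypes at 12 weeks 1 of 100 splits gave 72 genes or more, the real one, with 13 as the highest other. This met the rule for calling chance an unlikely source of that count in the full fit. The count was 15 without WT 12-week replicate 3 or KO 12-week replicate 6. For the 3 genes between stages in WT only the real split of those drawn gave as many (1 of 100, highest other 1), which met the same rule. That count was 1 without WT 6-week replicate 2 or with the deposition run as a block, and 0 with sex and deposition run together. Chance is therefore not called excluded for it. In KO 2 of 84 splits gave 1 gene, the real one and 1 other, so the real count did not exceed the highest other. At 6 weeks 5 of 35 splits gave 7 genes or more, so chance could not be excluded for that count. The highest other split, WT replicates 3 and 4 with KO replicate 2 against the rest, gave 1135 genes. This points to a structure of the samples other than genotype. Those arrays had the highest mature oligodendrocyte and myelin scores of 6 weeks (1.52, 2.01 and 1.24). Their neuron scores were the lowest of that stage (−0.51, −0.70 and −1.33). For lists, chance could not be excluded in any comparison: 7 of 35 splits gave as many as the 17 at 6 weeks (highest other 21), 5 of 100 as many as the 16 at 12 weeks (17), 5 of 100 as many as the 17 between stages in WT (18), and 39 of 84 as many as the 11 in KO (22). For the interaction 43 of 100 splits gave as many as 851 genes by unadjusted p, with 3101 as the highest other. A split of the 12-week arrays by sex in the fit of all arrays gave 0 genes and 1 list, but that fit missed even Xist (adjusted p = 0.214), because the groups of 6 weeks hold both sexes and widen its spread. The split by deposition run there gave 0 genes and 5 lists. In a fit of the 12-week arrays alone, run after this was seen, genotype gave 234 genes and 16 lists, deposition run 1 gene (Nts) and 4 lists, and sex 4 genes, all sex-linked (Xist, Eif2s3y, Kdm5d and Uty), and 3 lists.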
